A study of Mus musculus with 6 samples.

How the data were processed

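RNA was measured in 6 libraries of mouse embryonic stem (ES) cells of the C57BL/6 strain, 3 from wild-type (WT) cells and 3 from cells in which Mpp8 and Tasor were both knocked out (dKO). Per the labels' protocols, cells were flash frozen, RNA was taken up in Trizol, and libraries were made from total RNA with an Illumina TruSeq RNA kit. The series' design text names an Illumina Novaseq6000 sequencer. Whether the kit selected polyadenylated RNA and whether reads were counted by strand is not given in the sources used here.

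The submitters' processing notes name FastQC, HISAT2 2.1.0, RSEM, DESeq 1.26.0 and the genome build GRCm39, without saying what each was used for. The gene annotation release is not given in the sources used here. The authors deposited 1 table of 57180 genes with a symbol and an Ensembl identifier per gene. Its expected counts, per the file headers and the authors' naming of RSEM, are estimated counts of reads per gene that need not be whole, and 24.6% of the values above 0 were not exactly whole as printed, with no tolerance. The deposited table also gives TPM per library and the authors' mean TPM per genotype. These were not used for any test. A gene length in bases, per the file headers, was used for a length check. Per the file headers, the authors also give their own comparison of dKO with WT: a fold (ratio), its log2 value, a p-value and an adjusted p-value. That comparison is quoted only as the authors' deposited table.

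Estimated counts were rounded to whole numbers. In the rounded table, 28491 genes had a count of 0 in all 6 libraries. Total counts per library ran from 18384804 to 24910541. A count of 0 allows up to 3 counts in that library, which is 0.12 to 0.163 CPM (counts scaled to a common library total) depending on the library. Such floors cover counting error only. Estimated counts share reads between near-identical genes by a model, so values of paralogs, retrocopies and multigene families are uncertain as single genes. Reads of overlapping and antisense genes are likewise uncertain.

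Gene tests used edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by genotype, which left 15714 genes tested. Libraries were scaled with TMM factors, and dispersions and the quasi-likelihood fit were estimated with robust settings on a design with genotype only. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Fold changes are dKO over WT on the log2 scale. Their standard error (SE) is the size of the log2 fold change divided by the square root of the quasi-likelihood F statistic. CPM values are scaled by the TMM factors and are given as mean ± SD over 3 libraries. For a gene at 0 in all libraries of a genotype, the fold is a lower bound against 3 counts over that genotype's 3 libraries together. The common biological coefficient of variation was 0.156.

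Before the data were examined, 24 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with 5 or more tested members were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 22 lists. Camera was repeated with a correlation estimated per list, and fry, which tests whether a list's genes move one way on balance, was run beside it. Member counts are also given adjusted over the list alone. The named genes are the HUSH list, the 12 largest rises and the 12 largest falls, the 4 genes with the smallest p, and up to 4 members with the smallest p in each list. Rises and falls were ranked among called genes with an average log2 CPM of 1 or more and no overlap between genotypes, leaving out symbols that are only an identifier, Gm numbers or Rik clones. Other genes are named as chosen after their values were seen.

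Chromosome, gene class and exon structure came from GENCODE M21 by Ensembl identifier, which matched 51933 of the 57180 genes. GENCODE M21 is on GRCm38, not the authors' build, so no coordinates are given and only the order of genes along a chromosome was used. Fisher's exact tests, two-sided, compared called genes on each chromosome and in each gene class with the other tested genes, higher and lower apart, with Benjamini-Hochberg adjustment. Windows were runs of 25 neighbouring tested genes. Longest exons of called and unchanged protein-coding genes were compared with a permutation test of 1e+05 resamples within 10 deciles of mean expression. Gene classes were tested again with calls of at least 2-fold only. These steps and all plots used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

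Steps were tested on simulated data drawn from the means, library sizes and dispersions of the 15714 genes of the dKO and WT comparison. Of 50 genes simulated at each size, 22% were recovered at 1.5-fold, 70% at 2-fold, 88% at 4-fold and 94% at 8-fold. Among the calls, 8.05% were unchanged genes. This simulation left 15514 of the 15714 genes unchanged, where 34.3% of genes changed in the real comparison. The adjusted threshold depends on that share, so the rates above need not hold for the real comparison. With all chromosome 14 genes simulated at the dose of 1 copy in place of 2, 72.8% were called lower. In that simulation, which also raised a small random list of genes, 1 test of another chromosome passed with more called genes than elsewhere.

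Alternatives were DESeq2's size factors in edgeR, library totals without TMM factors, the DESeq2 1.42.0 Wald test, no low-count filter, a filter of CPM above 1 in 3 libraries, a replicate block, and each library left out in turn. After the values were seen, the genes of chromosomes 14 and Y, and Mphosph8 and Tasor, were left out of the list tests as added alternatives. Within each genotype, no 2 libraries held identical counts, and pairs differed by 3.17 to 60.2 times the sampling noise (chi-square per degree of freedom, genes with a summed count of 20 or more). All 6 libraries therefore counted as separate. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Retroelement families, which the table does not list as genes, were not analysed here.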

Results

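Mouse ES cells were profiled by RNA sequencing in 3 WT and 3 dKO libraries. MPP8 (encoded by Mphosph8) and TASOR are, with Periphilin, core subunits of the human silencing hub (HUSH) complex, which keeps long retroelements such as LINE-1 and some genes silent in chromatin carrying H3K9me3. The comparison asks which transcripts differ between dKO and WT cells. Most tested genes of chromosome 14 and of the Y chromosome were also lower in dKO, as given below. The comparison does not separate effects of that from effects of the missing subunits. Total counts were 18384804, 24910541 and 18942889 in WT replicates 1, 2 and 3, and 20128374, 18881728 and 18887984 in dKO replicates 1, 2 and 3. The genotypes parted on the first principal component, which held 68.8% of the variance. The second, with 15.4%, placed WT replicate 2 at -45.2 and WT replicate 3 at 29.7, and the other 4 libraries between them. WT replicate 2 also had the highest share of mitochondrial counts (2.29%, against 1.34% to 1.63% elsewhere) and the lowest share of ribosomal protein counts (3.05%, against 3.94% to 5.42% elsewhere).

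Both targeted genes were lower in every dKO library than in any WT library. Mphosph8 (ENSMUSG00000079184, chromosome 14) fell from 128 ± 16 CPM in WT (SD, n = 3) to 0.138 ± 0.081 CPM in dKO (SD, n = 3), with estimated counts of 1, 4 and 3 in the 3 dKO libraries. Its log2 fold change was -9.82 (SE 0.247, edgeR quasi-likelihood adjusted p = 4.7e-08). Tasor (ENSMUSG00000040651, chromosome 14) fell from 162 ± 33.7 to 9.85 ± 1.04 CPM, a log2 fold change of -4.04 (SE 0.169, edgeR quasi-likelihood adjusted p = 5.62e-07), and kept 180, 196 and 204 counts. Which part of each gene was removed is not stated in the labels, so remaining reads give no measure of remaining protein.

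**Figure D1:**
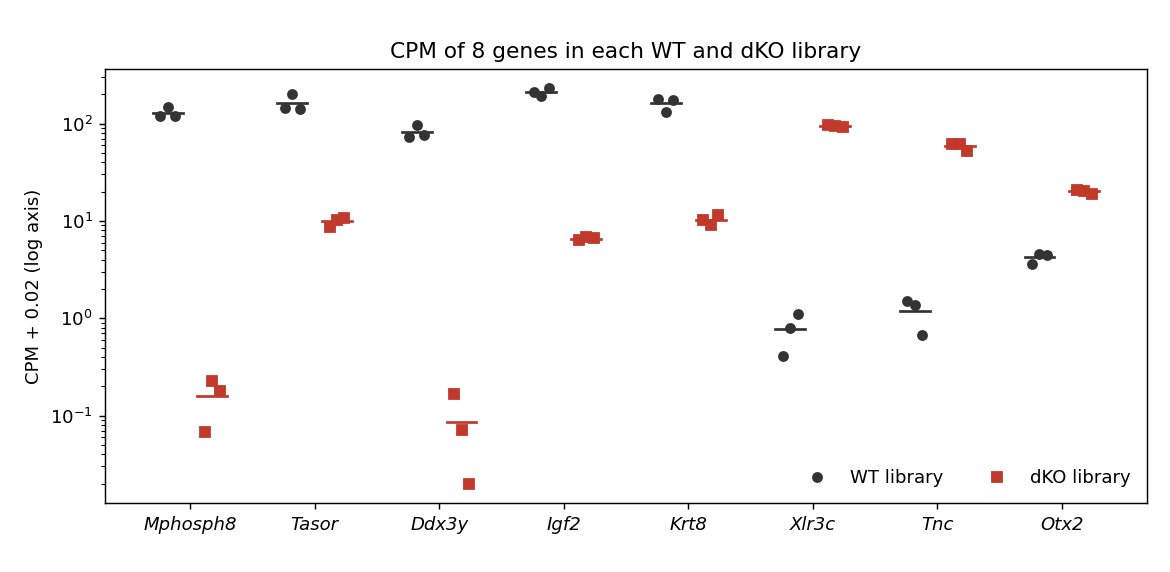
CPM of 8 genes in each of the 3 WT (circles) and 3 dKO (squares) libraries, on a log axis after adding 0.02, with a line at each mean. The dKO libraries lie below the WT libraries for Mphosph8, Tasor, Ddx3y, Igf2 and Krt8, and above them for Xlr3c, Tnc and Otx2.

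Of 15714 genes tested, 5391 (34.3%) changed in dKO by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 2578 were higher and 2813 were lower, and 2105 changed at least 2-fold (1118 higher, 987 lower). At an unadjusted p under 0.05 there were 6981 genes. In 49.2% of tested genes the 3 dKO libraries did not overlap the 3 WT libraries, where chance gives 10%. Without dKO replicate 1 there were 3586 changed genes, 1843 of them lower.

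**Figure D2:**
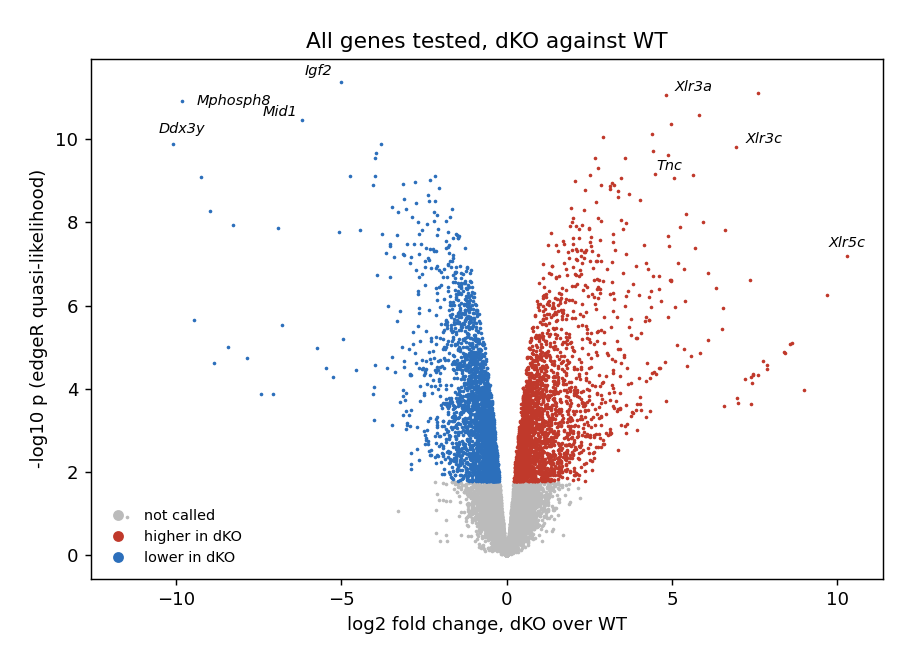
Each point is 1 of 15714 tested genes, with its log2 fold change (dKO over WT) on the x axis and -log10 of the unadjusted edgeR p on the y axis. Coloured points are the 2578 genes called higher and the 2813 called lower.

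The largest rises were led by X-linked genes of the Xlr and Fthl17 families, with Tnc, Inhba and several genes that were near 0 in WT. Xlr3c, a member of the lymphocyte-regulated cluster on the X chromosome, rose from 0.753 ± 0.356 to 93.9 ± 2.12 CPM (log2 6.95, SE 0.231, n = 3 each). Xlr3a rose from 2.92 ± 0.0569 to 82.4 ± 4.22 CPM and was among the 4 genes with the smallest p. Xlr4c (log2 5.71) and Xlr4a (log2 5.39) rose as well. Xlr5c had no counts in any WT library and 7.82 ± 0.336 CPM in dKO, at least 159-fold higher. Fthl17d, a ferritin heavy chain-like gene, was also at 0 in all WT libraries and reached 5.21 ± 0.93 CPM in dKO, at least 106-fold higher. Copies within each of these families are nearly identical, so the split of reads among members is uncertain.

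Autosomal genes among the 12 largest rises included Tnc, which encodes the matrix protein tenascin C and rose from 1.16 ± 0.444 to 58.5 ± 5.14 CPM (log2 5.63, SE 0.222). Inhba, the activin A subunit gene, rose from 0.169 ± 0.0486 to 7.42 ± 0.379 CPM. Cox7b2 and Ndufb11b, relatives of subunits of the respiratory chain, rose by log2 6.61 and 5.24. Tmem30c (log2 6.33), Trim43a (log2 6.10) and the olfactory receptor gene Or14j6 (log2 5.93) completed the 12. All of them were called by edgeR's test, with adjusted p from 2.01e-07 to 3.53e-05 over the 12 genes.

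Genes of the Y chromosome, Igf2 and Mid1 were among the largest falls. Igf2, the imprinted insulin-like growth factor gene, fell from 212 ± 18.6 to 6.58 ± 0.254 CPM (log2 -5.01, SE 0.113, edgeR quasi-likelihood adjusted p = 4.52e-08). Mid1, an X-linked ubiquitin ligase gene, fell from 149 ± 7.56 to 2.04 ± 0.558 CPM (log2 -6.19, SE 0.174), and Erdr1x, also X-linked and nearly identical to the Y-linked Erdr1y, so that the split of reads between them is uncertain, had a log2 fold change of -6.91. The Y-linked genes Ddx3y, Eif2s3y, Uty and Uba1y had log2 fold changes of -10.10, -9.25, -8.96 and -8.27, with at most 5 counts in any dKO library. Hand1 (log2 -5.07), a transcription factor gene of trophoblast and heart, Wnt7b (log2 -4.74) and Nkx6-3 (log2 -4.56) fell too. Pdcd5-ps, a processed pseudogene, had 4.41 ± 1.21 CPM in WT and no counts in dKO, at least 88.9-fold lower.

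Among 12 HUSH genes and partners, all tested, 3 rose and 4 fell, and 5 were not called (4 higher and 4 lower adjusted over the list alone). Besides the 2 targets, Trim28, the KRAB zinc finger corepressor, fell by 0.37 on the log2 scale (SE 0.0838) and the H3K9 methyltransferase gene Setdb1 fell by 0.29 (SE 0.0938). Morc2a, encoding the HUSH-associated ATPase, rose by 0.51 (SE 0.0867) and Atf7ip, encoding the SETDB1 cofactor, by 0.52 (SE 0.108). Morc2b, at 0.42 ± 0.32 CPM in WT, reached 1.73 ± 0.15 CPM. Periphilin (Pphln1) had a log2 fold change of -0.23 (SE 0.128), which was not called, and Resf1, Zfp638, Tasor2 and Atf7ip2 had values of 0.41, 0.28, -0.21 and -0.03. Camera called the list lower (adjusted p = 0.00618; adjusted p = 0.517 with an estimated correlation), and without Mphosph8 and Tasor, left out after the values were seen, its median was 0.13 with no call (adjusted p = 0.624, range over alternatives 7.22e-05 to 0.736). Calls were lost for Setdb1 in 8 of 12 alternative settings (adjusted p 0.00916 to 0.149) and for Morc2b in 4 of 12 (0.000537 to 0.0625), both without WT replicate 1 or any 1 dKO replicate, and for Trim28 without dKO replicate 1 (0.0563, range 0.00032 to 0.0563), while Resf1 was called higher in 5 of 12 settings (0.000129 to 0.185) and Zfp638 in 2 of 12 (0.000511 to 0.357), both with the replicate block and without WT replicate 2, and Resf1 also with library totals, by DESeq2 and without a low-count filter.

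Among 18 genes of heterochromatin and DNA methylation enzymes, 1 was higher, 7 were lower and 10 were not called (1 higher and 9 lower adjusted over the list alone). Dnmt3a, a de novo DNA methyltransferase, rose from 141 ± 14.1 to 216.5 ± 2.25 CPM (log2 0.61, SE 0.0928). Its partner Dnmt3l fell by 0.71 on the log2 scale (SE 0.13), the demethylase gene Tet2 by 0.72 (SE 0.132), and Smchd1, which acts in X inactivation, by 1.03 (SE 0.175). The list was not called by camera (adjusted p = 0.185), was called lower without a low-count filter (adjusted p = 0.0488, range over alternatives 0.00034 to 0.305), and fry called it lower (adjusted p = 0.00034).

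Most core and naive pluripotency genes were not called, while 8 of 15 formative and primed genes rose. Of 12 core pluripotency genes, 2 rose, 3 fell and 7 were not called (2 higher and 3 lower adjusted over the list alone). Dppa2 rose by 0.44 on the log2 scale, Fgf4 and Lin28a fell by 0.56 and 0.41, Tdgf1, chosen after its value was seen, fell by 0.37, and Pou5f1 and Sox2, the central factors of the pluripotent state, had log2 fold changes of 0.04 and 0.21. The list median was -0.04, its mean 0.04 and camera's direction up, with no call (adjusted p = 0.753). Of 18 naive genes, 2 rose, 3 fell and 13 were not called (2 higher and 3 lower adjusted over the list alone). Klf5, on chromosome 14, fell from 103 ± 10.5 to 33.7 ± 1.35 CPM, Tfcp2l1 fell by 0.79 and Stat3, chosen after its value was seen, fell by 0.34, while Fbxo15 and Spic rose by 0.73 and 1.24. The naive median was 0.09, its mean -0.03 and camera's direction down, with no call (adjusted p = 0.753).

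In the formative and primed list, 8 of 15 tested genes rose, 3 fell and 4 were not called (9 higher and 4 lower adjusted over the list alone). Otx2, which drives exit from naive pluripotency, rose from 4.2 ± 0.538 to 20.1 ± 1.01 CPM (log2 2.25, SE 0.145). Lef1, a Wnt effector, rose by 2.70 on the log2 scale (SE 0.244), Zic2 by 1.39 (SE 0.124) and Tead2 by 0.99 (SE 0.11). The 3 lower genes, chosen after their values were seen, were Cdh2 (log2 -0.62), Sall2 (log2 -0.41, chromosome 14) and Dnmt3b (log2 -0.33). Camera called the list higher (adjusted p = 0.00245; adjusted p = 0.246 with an estimated correlation). Without the genes of chromosomes 14 and Y, an alternative added after the values were seen, its camera adjusted p was 0.0855 (range over alternatives 9.05e-05 to 0.246). The list's median was 0.46 both with and without those genes.

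Trophoblast genes showed the broadest fall among the lineage lists, with 12 of 16 tested members lower, 1 higher and 3 not called (12 lower and 1 higher adjusted over the list alone). Krt8, a keratin of simple epithelia, fell from 162 ± 26.9 to 10.3 ± 1.19 CPM (log2 -3.98, SE 0.157), Krt18 from 96.9 ± 23.5 to 12 ± 0.419 CPM and Krt7 from 16.7 ± 3.86 to 1.32 ± 0.212 CPM, and Hand1 is given above. The 1 higher member, chosen after its value was seen, was Prl2c2, a placental prolactin family gene with no WT counts and 1.48 CPM in dKO, at least 29.9-fold higher, whose reads can be shared with close copies. The median log2 fold change was -1.38, also with Prl2c2 at its bound, and camera called the list lower (adjusted p = 1.61e-12; adjusted p = 0.0938 with an estimated correlation). Primitive endoderm genes fell in 8 of 16 cases, rose in 2 and were not called in 6 (8 lower and 2 higher adjusted over the list alone). The basement membrane genes Lama1 (log2 -2.17, SE 0.0859), Col4a1 (log2 -1.60, SE 0.167), Lamb1 (log2 -1.08, SE 0.0765) and Sparc (log2 -0.81, SE 0.0795) fell, while Pdgfra and Cubn rose by 1.34 and 1.30. The endoderm factor genes were all chosen after their values were seen, as were Pdgfra and Cubn. Sox7 and Gata4 on chromosome 14 fell by 2.89 and 1.49 on the log2 scale, and Foxq1 on chromosome 13 fell by 1.69. Gata6 had a log2 fold change of 0.54 and was not called. Camera called this list lower (adjusted p = 0.00168; adjusted p = 0.0938 with an estimated correlation).

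In the primitive streak and mesoderm list 6 of 10 tested genes rose, 1 fell and 3 were not called (6 higher and 1 lower adjusted over the list alone). Lefty1 rose from 40.2 ± 13.1 to 192 ± 29.2 CPM, Lefty2 from 68 ± 7.74 to 153 ± 8.67 CPM and Nodal from 40.4 ± 5.55 to 84 ± 4.26 CPM. The lower gene was Hand1 (log2 -5.07), the list's largest change. The list was not called by camera (adjusted p = 0.0966), while fry called it higher (adjusted p = 0.00141). Neural genes went both ways, with 3 higher, 3 lower and 6 not called among 12 (3 higher and 4 lower adjusted over the list alone): Pax6 rose by 1.19 and Map2 by 0.67, and Olig2 and Stmn2 fell by 2.64 and 0.77 on the log2 scale. Nes and Sox11, chosen after their values were seen, had log2 fold changes of 0.38 and -0.45. Camera gave an adjusted p of 0.556 for them. Fibroblast and feeder genes were higher in 8 of 19 cases and lower in 1, with 10 not called (10 higher and 1 lower adjusted over the list alone). Prrx1, a mesenchymal factor, rose from 0.137 ± 0.0728 to 2.51 ± 0.0831 CPM, and Fbn1, Acta2 and Col1a2 rose by log2 1.20, 1.18 and 1.02, while Col1a1, the most abundant fibrillar collagen of fibroblasts, was at 15.2 CPM in WT and 13.8 CPM in dKO and was not called. Col1a1 and the 1 lower gene, Tagln (log2 -0.65), were chosen after their values were seen. Camera called this list higher (adjusted p = 0.015; adjusted p = 0.294 with an estimated correlation), and the call was lost without WT replicate 2 (adjusted p = 0.0932, range over alternatives 0.00176 to 0.294).

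Imprinted genes were lower in 18 of 35 tested cases, higher in 6 and not called in 11 (18 lower and 9 higher adjusted over the list alone). With Igf2, the placental gene Peg10 fell from 866 ± 136 to 165 ± 13.3 CPM and Sfmbt2 from 130 ± 23.3 to 29.6 ± 1.22 CPM, and Mest rose from 18.3 ± 1.79 to 52 ± 2.54 CPM. Camera called the list lower (adjusted p = 0.00104; adjusted p = 0.0938 with an estimated correlation). Germline genes split into 9 higher, 10 lower and 9 not called among 28 (9 higher and 10 lower adjusted over the list alone). Rpl10l rose from 9.76 ± 3.06 to 146 ± 21 CPM, D1Pas1 from 13.8 ± 1.52 to 99.3 ± 6.6 CPM and the meiotic cohesin gene Smc1b from 5.44 ± 1.1 to 37.4 ± 5.56 CPM, while Ddx4, a germ cell RNA helicase, fell from 46.9 ± 4.85 to 11 ± 0.547 CPM. Rpl10l and D1Pas1 are intronless copies of Rpl10 and Ddx3x and can share reads with them. The germline median was -0.07, its mean 0.05 and camera's direction up, with no call (adjusted p = 0.401).

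Of 33 genes of the 2-cell-like list, the transcripts of a rare state in ES cultures, 6 had enough counts for a test, and 5 rose, 1 fell and 0 were not called (5 higher and 1 lower adjusted over the list alone). Pramel6 (log2 4.92, SE 0.3), Pramel7 (log2 3.78, SE 0.364) and Obox6 (log2 2.76, SE 0.217) rose, as did Sp110 (log2 3.02) and Zfp750 (log2 0.61), chosen after their values were seen, and Calcoco2, an autophagy receptor gene, fell by 1.16 (SE 0.0996). The Zscan4 genes, the best known markers of that state, were too low to test, with 0.055 ± 0.095 CPM in WT and 0.602 ± 0.385 CPM in dKO summed over 10 members (39 counts in all, genotypes overlapping). Also summed over members, and chosen after their values were seen, Tdpoz genes had 0.233 ± 0.038 CPM in WT and 3.87 ± 0.553 CPM in dKO and Usp17l genes 0.105 ± 0.086 and 0.576 ± 0.181 CPM, neither overlapping between genotypes, where chance gives 10%. Most of the Tdpoz counts were those of Tdpoz6, which is not in the list (log2 4.01, SE 0.33). Reads of Pramel genes can be shared between close copies. Pramel6, Pramel7 and Sp110, at 0.201, 0.205 and 0.064 CPM in WT, passed the low-count filter only through their dKO libraries. The share of higher members is therefore partly set by the filter. Camera called the list higher (adjusted p = 0.00104; adjusted p = 0.0938 with an estimated correlation). The list was called in 14 of 15 alternatives, the one without a low-count filter among them.

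Interferon and double-stranded RNA response genes were mostly not called, with 3 of 27 tested genes higher, 5 lower and 19 not called (3 higher and 5 lower adjusted over the list alone). The other 16 of 43 had too few counts for a test. Among them, chosen after their values were seen, were Rsad2 (6, 4 and 5 counts in WT, 19, 21 and 7 in dKO), Ifit1 (4, 4 and 4 against 14, 7 and 6) and Mx2 (2, 0 and 0 against 9, 13 and 10). Cxcl10 had 4, 7 and 9 counts against 25, 9 and 15, and Ifih1 17, 12 and 4 against 1, 6 and 5. Of these 16, only Ifih1 had fewer counts in dKO summed over libraries. Most of the others had more, at low counts, and 3 had none in any library. Oas1a rose from 3.81 ± 0.164 to 10.5 ± 1.04 CPM, and Ifitm3, Sting1 and Irf9 (chromosome 14) fell by 1.14, 1.02 and 0.96 on the log2 scale. Chosen after their values were seen, Ifi35 and Stat2 rose by 0.65 and 0.38, Ifit2 and Oas3 fell by 0.80 and 0.57, and the sensor genes Eif2ak2 and Rigi had log2 fold changes of 0.14 and 0.13 and were not called. The list median was -0.00011, its mean -0.06, and camera gave an adjusted p of 0.997. Without a low-count filter the median was 0.16, also with no call (adjusted p = 0.616, range over alternatives 0.616 to 0.998). Genes of the p53 response were higher in 10 of 23 cases, lower in 3 and not called in 10 (12 higher and 3 lower adjusted over the list alone). Trp53inp1 rose by log2 0.91, and Perp, Tnfrsf10b and Rrm2b fell by 1.43, 0.91 and 0.88 on the log2 scale. Camera gave this list an adjusted p of 0.189 and fry called it higher (adjusted p = 0.000824). Immediate early and heat shock genes had 1 higher (Egr1, from 35.6 ± 1.11 to 86.6 ± 3.77 CPM), 6 lower, among them Jun, Dusp1 and Hsph1, and 10 not called (1 higher and 6 lower adjusted over the list alone), with a camera adjusted p of 0.332 (0.0492 without WT replicate 2, range over alternatives 0.0492 to 0.858).

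Zinc finger genes named Zfp included 52 higher, 36 lower and 298 not called among 386 tested (43 higher and 30 lower adjusted over the list alone), and camera made no call (adjusted p = 0.619). Zfp229 rose from 15.5 ± 2.53 to 87.7 ± 4.45 CPM and Zfp773 by log2 1.77, and Zfp800 and Zfp395 fell by 1.30 and 0.90. None of the 22 protocadherin beta genes had enough counts for a test. The 22 tested alpha and gamma protocadherin genes had 0 calls by edgeR's quasi-likelihood test or by DESeq2 and 1 at an unadjusted p under 0.05, Pcdhgc4 (log2 0.40, edgeR adjusted p = 0.0516, camera adjusted p of the list 0.619). That gene was called in 5 of 12 alternative settings, among them without WT replicate 2 (adjusted p = 0.0134, range 0.0134 to 0.138). Of 39 Hox genes 3 were tested and Hoxc13 rose from 0.653 ± 0.091 to 1.89 ± 0.458 CPM (1 higher and 0 lower adjusted over the list alone).

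Ribosomal protein genes had 4 higher, 0 lower and 81 not called among 85 (2 higher and 0 lower adjusted over the list alone), with 1 lower by DESeq2 and 1 at an unadjusted p. Rpl10l, Rpl39l, Rps12l1 and Rps29 made up the 4, and the calls of Rps12l1 and Rps29 were lost in 2 and 5 of 12 alternative settings, both of them without WT replicate 1 or dKO replicate 3 and that of Rps29 also without WT replicate 2 or dKO replicate 1. The list median was -0.0099, its mean 0.07 and camera's direction up (adjusted p = 0.619). Without WT replicate 3 camera called it higher (adjusted p = 0.0158, range over alternatives 0.0158 to 0.962), and without WT replicate 2 its median was -0.20. Of 15 tested mitochondrial genes, mt-Rnr2 (log2 0.77, SE 0.153) and mt-Atp8 (log2 0.77, SE 0.234, lost in 6 of 12 alternative settings) were higher and 13 were not called (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.619). The list fixed for replication-dependent histone genes had 1 higher (H1f10, which encodes a replication-independent linker histone), 3 lower and 10 not called among 14 (1 higher and 3 lower adjusted over the list alone), and camera gave an adjusted p of 0.485. The 3 were H1f2 (log2 -1.31), H2ac25, which had no counts in dKO and was at least 20.4-fold lower, and H2bc21 (log2 -1.46), whose call was lost in 6 of 11 settings. The histone list's median was -0.72, also with H2ac25 at its bound. Over the alternatives it ran from -1.08 to -0.13, the latter at CPM above 1 in 3 libraries, where camera's direction was up (adjusted p = 0.966, range over alternatives 0.127 to 0.966). Over all lists camera called 8 of 22, with 0 called and 5 at an unadjusted p under 0.05 when the correlation was estimated, and fry called 11.

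**Figure D3:**
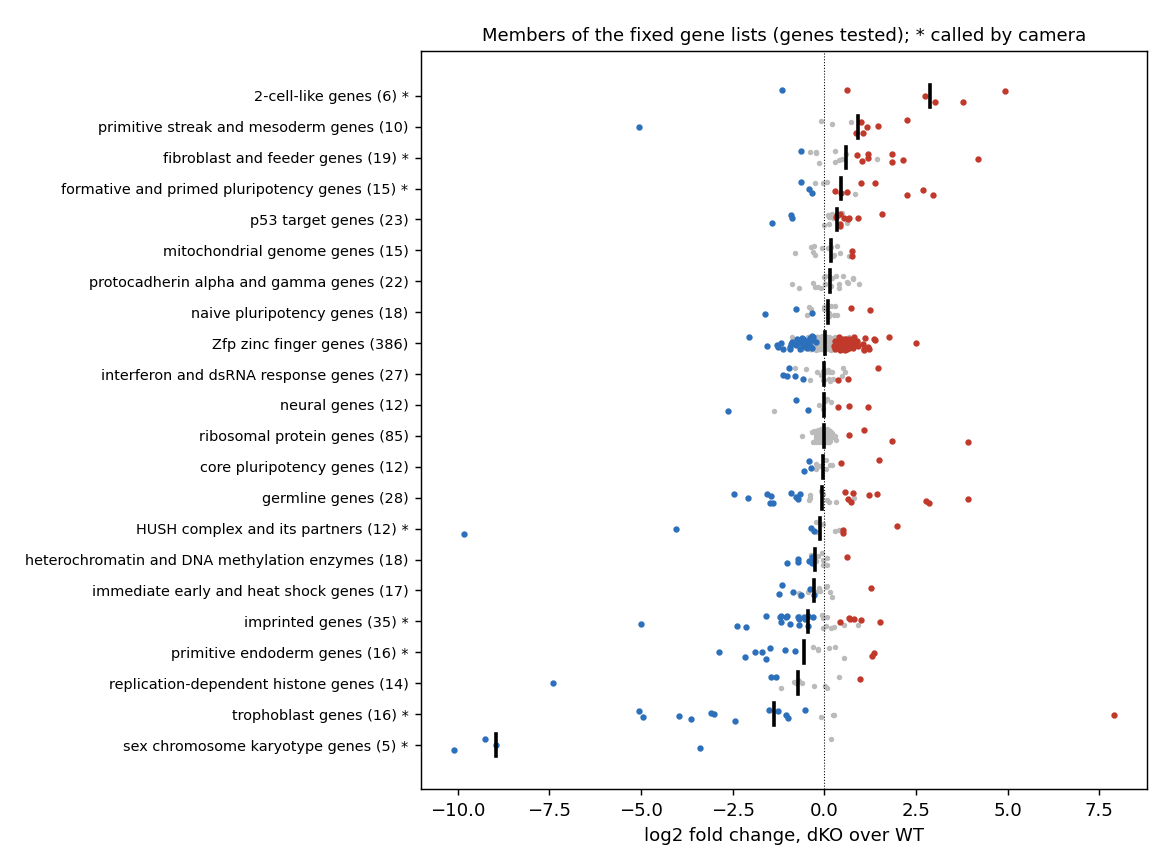
Log2 fold changes (x axis, dKO over WT) of the tested members of each fixed list with 5 or more of them, whose number stands in brackets, with a bar at each list's median. Coloured points were called by edgeR, and a star marks the 8 lists called by camera with the preset correlation.

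Most tested genes of chromosome 14, on which both targeted genes lie, were lower in dKO. Of its 525 tested genes, 370 (70.5%) were lower in dKO, against 16.2% elsewhere (odds ratio 12.3, Fisher's exact test, adjusted p = 4.67e-158), and 32 were higher. Their median log2 fold change was -0.94 (quartiles -1.29 and -0.50). Among 180 abundant chromosome 14 genes, with an average log2 CPM of 5 or more, the median was -0.98 and 92.2% were below 0, where abundant genes of the other autosomes had a median of -0.03. Counts on chromosome 14 made up 2.71 ± 0.0485% of the total in WT and 1.61 ± 0.0007% in dKO (n = 3 each, exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give). A run of 75 neighbouring genes from Dnase1l3 to Tmem254 had a median of -0.12, with 16 lower and 13 higher, while the other 450 genes, both targets among them, had a median of -1.02. Chromosome 14 also held the named genes Klf5, Tnfrsf10b, Irf9 and Zfp395, which fell, and Otx2 and Zic2, which rose. On the Y chromosome 9 of 12 tested genes were lower (adjusted p = 0.000277, Fisher's exact test) and the median was -8.06. Of the sex chromosome list 4 of 5 genes fell, Ddx3y, Eif2s3y, Uty and Kdm5d (4 lower and 0 higher adjusted over the list alone), and Xist, chosen after its value was seen, had a log2 fold change of 0.17 and was not called. Kdm5d kept 46 to 62 counts per dKO library and can share reads with its X-linked relative Kdm5c. Camera called that list lower (adjusted p = 3.2e-24; adjusted p = 0.0938 with an estimated correlation). The X chromosome had a median of -0.05. Over all chromosomes 10 of 42 tests passed, the others being fewer lower genes on chromosomes 2, 4, 5, 7, 10 and 17 (odds ratios 0.655 to 0.806, against genes elsewhere that include the lower genes of chromosome 14), more higher genes on 10 (1.33) and fewer on 14 (0.326). In the simulation with chromosome 14 lowered, 1 test of another chromosome also passed with more called genes than elsewhere, so a single such result is uncertain. Without the genes of chromosomes 14 and Y, 4979 genes were changed, 2545 higher and 2434 lower. All 3 dKO libraries shared the shifts on chromosomes 14 and Y. Changes of other genes therefore cannot be split between the knockout and indirect effects of these shifts.

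**Figure D4:**
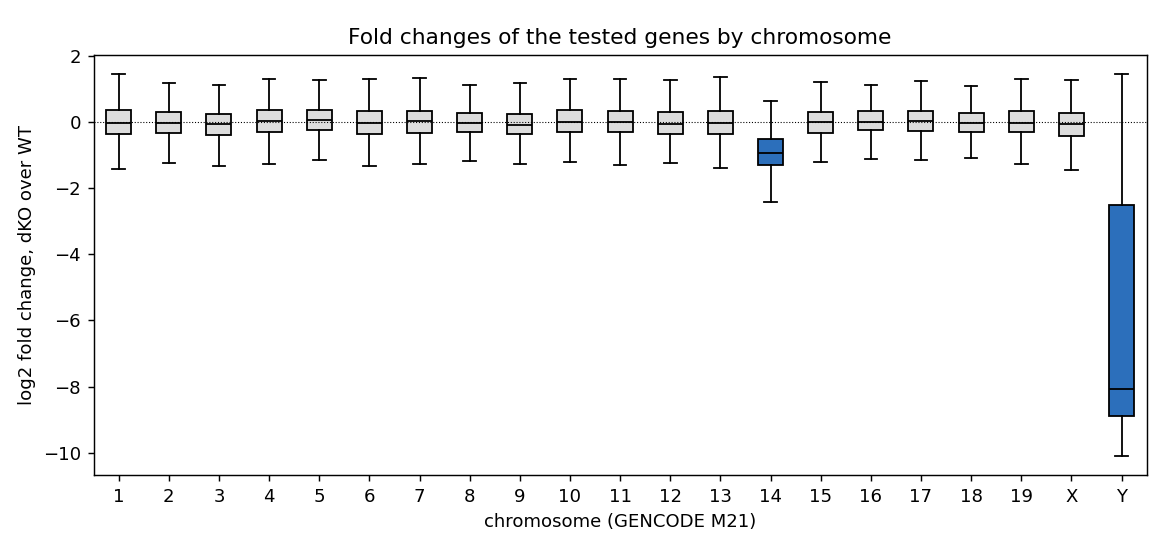
Log2 fold changes (y axis, dKO over WT) of tested genes by chromosome, as boxes from the lower to the upper quartile with a line at the median and whiskers reaching the furthest gene within 1.5 interquartile ranges. Chromosome 14 (median -0.94) and Y (median -8.06) are coloured.

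**Figure D5:**
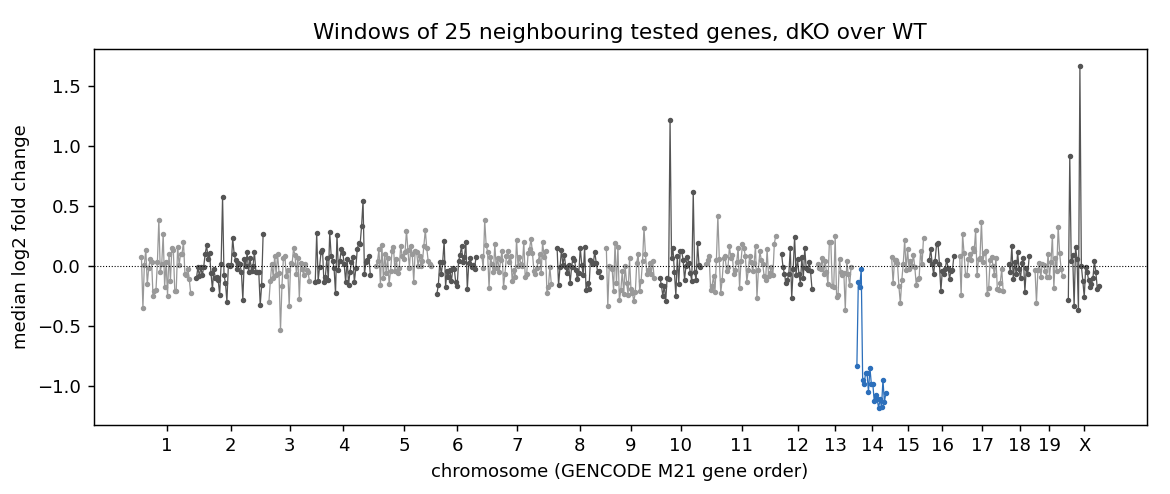
Median log2 fold change (y axis) of windows of 25 neighbouring tested genes in their order along each chromosome (x axis). On chromosome 14, 18 of 21 windows lie under -0.5, against 1 of 584 windows elsewhere.

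Gene classes differed in the share that rose. Processed pseudogenes, which are intronless copies of mRNAs, were higher in 32.7% of 324 tested cases against 15.9% of the other genes (odds ratio 2.57, Fisher's exact test, adjusted p = 3.34e-13), and long non-coding RNA genes in 23.8% of 921 against 15.8% (odds ratio 1.67, adjusted p = 2e-09, same test). Protein-coding genes were higher in 15.1% and lower in 19.5% of 13750 cases. Single-exon protein-coding genes, of interest because HUSH has been linked to long intronless DNA, were higher in 16.0% of 306 cases against 15.1% of multi-exon genes (adjusted p = 0.628, Fisher's exact test). The odds ratio of their rises, with calls of any size, was 1.075. It was 1.02 with DESeq2's size factors and 1.06 without chromosomes 14 and Y, neither called. With calls of at least 2-fold only, run in the main fit alone, it was 2.15 (adjusted p = 0.000514, Fisher's exact test). Pseudogenes other than processed ones went from 1.27 with calls of any size, not called, to 3.36 with 2-fold calls (adjusted p = 0.000261, Fisher's exact test). The longest exon of higher genes was 1.03 times that of unchanged genes matched on expression (permutation test, p = 0.116, adjusted p = 0.116), and that of lower genes 1.08 times (p = 1e-05, the smallest that 1e+05 resamples can give, adjusted p = 2e-05). Reads of a processed pseudogene can come from its parent gene, so single members of that class are uncertain.

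The authors' deposited table gives an adjusted p under 0.05 for 5313 genes, 2669 higher and 2644 lower. Of the 5391 genes called here, 4987 (92.5%) were also called in the authors' deposited table, all 4987 in the same direction. The authors' deposited table gives log2 fold changes of -9.88 for Mphosph8 and -4.03 for Tasor.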

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

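Leaving out the genes of chromosomes 14 and Y, and leaving out Mphosph8 and Tasor, were tests chosen only after the result was seen. Of 116 named genes, 103 kept their direction and their side of the threshold in every alternative run for them, Mphosph8 (-10.23 to -9.41) and Tasor (-4.14 to -3.86) among them. Of the 5391 changed genes, 5248 were also called with DESeq2's size factors, 4971 with library totals, 4975 by the DESeq2 test, 4986 without a low-count filter and 5081 with CPM above 1 in 3 libraries, and no gene was called in the opposite direction. With library totals 55.9% of calls were higher, against 47.8%. Leaving out 1 library gave 3586 to 6828 changed genes and 1843 to 3468 lower genes, the lowest counts without dKO replicate 1 and the highest without WT replicate 2, and fewer libraries alone lower such counts. The series' design text gives no pairing of libraries. Deviations of same-numbered libraries correlated at -0.076, 0.273 and 0.329, and those of different-numbered libraries at -0.406 to 0.215. The values of 0.273 and 0.329, for replicates 2 and 3, lay above all those of different-numbered libraries. Replicates 2 and 3 also deviated with gene length in the same direction in both genotypes, as given below. Same-numbered libraries may thus share an effect that the main design leaves out, and whether that was a batch stays open. With the replicate block 6794 genes changed, 3299 of them higher and 3495 lower. Of the lists, 0 were called with an estimated correlation and 5 without chromosomes 14 and Y, where the sex chromosome list had too few genes left for a test. At 18384804 to 24910541 counts per library, 22% of simulated changes of 1.5-fold and 70% of those of 2-fold were called, with 15514 of 15714 genes left unchanged. A larger share of genes changed in the real comparison, so these rates need not hold there.

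Some list and gene values near 0 changed sign or camera's direction turned, and the cause was not tested except where given. Without WT replicate 2, Tasor2 came to 0.025, Atf7ip2 to 0.117 and the core pluripotency median to -0.124. Over the libraries left out, these ran from -0.33 to 0.025, from -0.11 to 0.117 and from -0.124 to 0.10. With library totals Atf7ip2 came to 0.029. Without chromosomes 14 and Y the HUSH list came to 0.13, the naive list to 0.109 and the interferon list to 0.018, and without Mphosph8 and Tasor the HUSH list again came to 0.13, since its 2 deepest falls are then missing. The interferon list came to 0.16 without a low-count filter, 0.030 with CPM above 1 in 3 libraries, and -0.0065 to 0.193 with 1 library left out. Ribosomal protein genes ran from -0.201 to 0.251 with 1 library left out, and histone genes came to -0.129, with camera's direction up, at CPM above 1 in 3 libraries, where fewer members are tested.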

Other observations

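The tests of gene families by symbol, of a copy missing along the whole of chromosome 14, of windows on other chromosomes, of single chromosome 14 responses, of trophoblast members on chromosomes 14 and Y, of fewer trophoblast-like cells and of a second X chromosome were chosen only after the result was seen. Gene families were formed from the letters that open a symbol, and 441 families with 5 or more tested genes were compared with the other genes by Fisher's exact test, one-sided in each direction. Of 882 tests, 5 passed Benjamini-Hochberg adjustment. Keratin genes were lower in 10 of 15 cases (median -2.0, adjusted p = 0.0167), among them Krt19 and the keratins named above. Annexin genes, which encode calcium-dependent membrane binding proteins, were lower in 8 of 10 cases (median -0.72, adjusted p = 0.0167), 3 of the 10 lying on chromosome 14. Vomeronasal receptor genes, which are normally silent outside the sensory organ of the nose, were higher in 15 of 35 cases (median 0.81, adjusted p = 0.0167), and as a large family of close copies they can share reads. The other 2 were the Xlr and Fthl17 families, with 8 of 8 and 6 of 7 tested genes higher and Fthl17a, the seventh, lower (log2 -2.36). Members near 0 in WT, such as Xlr5c and Fthl17d, passed the low-count filter only through their dKO libraries. In families with low WT counts, the share of higher members is therefore partly set by the filter. Copies that share reads are also not independent, so the p-values of such families are uncertain.

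Windows of 25 neighbouring genes also stood out away from chromosome 14. A window of chromosome 10 from Gm47503 to Gm47738 had a median of 1.21, another on chromosome 10 from Gm47578 to E2f7 one of 0.62, a window of chromosome 2 from Gm19426 to Agbl2 one of 0.57, and a window of chromosome 4 from Zfp986 to Zfp978 one of 0.54. On the lower side a window of chromosome 3 from Trim59 to Plrg1 had a median of -0.54, with 80% of genes below 0. The X-linked windows that hold the Xlr genes (Gm1141 to Bgn) and the Fthl17 genes (Timm17b to Fthl17f) had medians of 1.66 and 0.91. These windows were picked after their values were seen. Across genes, the deviation of a library from its genotype followed gene length in replicates 2 and 3 of both genotypes. Spearman's rho was 0.289 in WT replicate 2 and 0.295 in dKO replicate 2, and -0.341 in WT replicate 3 and -0.299 in dKO replicate 3. In replicate 1 it was -0.031 for WT and 0.105 for dKO. Genes are not independent replicates, and the log2 fold change itself had a rho of -0.023 with length.

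Genes of chromosome 14 were lower together. Library scaling or WT replicate 2 is argued against, since the highest chromosome 14 median over library totals, DESeq2's size factors and the libraries without WT replicate 2 was -0.874. Separate responses of single genes are argued against by an upper quartile of -0.495, though the bounds for this were set after the values were seen. A copy missing along the whole length is argued against by 3 neighbouring windows, Dnase1l3 to Tmem254. These were picked for the highest median, and the bounds were set after the values were seen. Their 75 genes had a median of -0.116 (quartiles -0.38 and 0.32), while the other 450 genes had a median of -1.02 (quartiles -1.35 and -0.70). Over the whole chromosome 85.7% of windows lay under -0.5, between the bounds of 90% and 80% set for and against a missing copy. That share counts the 3 windows just named, so it does not bear on the rest of the chromosome alone. The median of the other 450 genes lay near -1, the chromosome 14 median simulated for 1 copy in place of 2. A copy missing in only a small share of the cells would give a smaller fall, and the median of -1.02 argues against it for these 450 genes. A missing copy over the rest of the chromosome may account for the pattern and stays open, since only RNA was measured.

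Of 16 tested trophoblast genes, 12 were lower in dKO, 1 was higher and 3 were not called, and camera's call of the list was lost with an estimated correlation (adjusted p = 0.0938 with an estimated correlation). WT replicate 2 alone is argued against by a median of -1.47 without it. Indirect effects of any lost copies of chromosome 14 or Y stay open: no tested member lies there, so the share of lower members there (0%) was fixed by the list. A lower share of trophoblast-like cells in the dKO cultures cannot be told apart from lower expression in the ES cells, since either would lower these genes in RNA of whole cultures. Of the members 75% were lower, short of the 80% set for fewer such cells and above the bound set against it. Both bounds were set after the values were seen, so that share decides nothing. An effect of the double knockout itself stays open and was not tested further.

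Xlr and Fthl17 genes were higher in dKO. Reads moved between near-identical copies are argued against, since counts summed over 16 Xlr members went from 7.66 ± 0.619 to 280 ± 6.72 CPM (log2 5.19) and those over 9 Fthl17 members from 4.53 ± 1.97 to 85 ± 8.01 CPM (log2 4.23), without overlap between genotypes (n = 3 each). A second X chromosome is argued against by the X-linked median of -0.051, though the bounds for this were set after the values were seen. An effect of the double knockout itself stays open, as do indirect effects of any lost copies of chromosome 14 or Y, and neither was tested further.

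The 6 libraries can be split into groups of 3 in 10 ways, and 1 of the 10, the real one, gave as many as 5391 changed genes. The highest of the others gave 0 by edgeR's quasi-likelihood test, with 37 to 1391 genes at an unadjusted p under 0.05. The 10 splits are too few for a share under 0.05.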
